A study of Homo sapiens with 12 samples.

How the data were processed

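The samples were 12 chromatin preparations of the MV4;11 cell line, from cells grown with 0.1% DMSO, 500 nM I-BET151, 5 µM SGC0946 or both compounds. Per the labels' protocols, cells were cross-linked with formaldehyde, chromatin was sonicated and immunoprecipitated, and libraries were made with a ThruPLEX kit. A peak list was used for 11 of them: H3K79me2 and Pol II under the 4 treatments, H4K5ac with DMSO and with SGC0946, and H3K27ac with DMSO. The input DNA sample was not analysed here. Groups were taken from the sample titles, which give the antibody and the treatment, and each group had 1 library.

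BWA 0.6.2-r126, MACS2 and the genome build hg19 are named in the submitters' processing notes. The MACS2 version, the control, the peak mode (narrow or broad) and any filter are not given in the sources used here. Each deposited list holds the peaks of 1 library, so peaks were called per library and not on pooled samples. The score of each peak is the authors' own, a −log10 value of the kind that MACS2 deposits, taken from its range: the lowest score of all lists was 1.304, just above 1.301, which is −log10 of 0.05. Whether it stands for a p-value or a q-value is not stated. A −log10 score grows with read depth, so scores were used to describe, rank and filter peaks within a list. The numbers of peaks of score 50 or more are set side by side for H4K5ac only, and the alternative with a stricter score carries the same reservation.

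Peaks on chromosomes 1 to 22, X and Y were used; peaks on other sequences were left out of the comparisons and numbered 53 to 207 per library, and 8 in the Pol II library of the combination lay on mitochondrial DNA. Values by chromosome are given for 1 to 22 and X. A reference peak was counted as overlapped when a peak of the other library shared at least 1 base with it, and as lost otherwise. Shares carry 95% exact (Clopper-Pearson) binomial intervals, which treat peaks as independent and hold no biological or technical variation between libraries. For each share, the peaks of the other library were also moved around each chromosome by a random distance 100 times with a fixed seed, and the mean share of these shifts is given. Covered length is the number of bases under at least 1 peak. Percentages of covered length set the totals of the libraries side by side, new peaks included. Covered length moves with how much was called in a library, and peak numbers are therefore given beside it.

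No genome or annotation on hg19 was used here, and the gene table at hand is on another build, so peaks were not assigned to genes and no gene names are attached to regions. The gene lists fixed beforehand were therefore not used. In their place, as planned for this case, the genome was divided into windows of 100 kb (30646 in all), and the length covered in each was compared. A window was counted as changed when its covered share differed by at least 10 percentage points. The windows named are the 8 with the largest loss and the 4 with the largest gain of covered length per comparison with DMSO, and the peaks named are among the 5 with the highest score in a library. This rule was set before the data were examined; the widest domain was named after its width was seen.

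DMSO Pol II peaks were split by whether they overlapped DMSO H3K27ac and H3K79me2 peaks. Peaks were also divided by DMSO score into 10 groups of equal size (deciles), and by width into classes up to 1, 5 and 10 kb and above. Losses shared by I-BET151 and SGC0946 were set against the number expected if both were independent, over all peaks, within score deciles and within groups of equal score and width. Unchanged libraries to simulate the effect of the shared DMSO library could not be had, since no group has replicates. No test across treatments was possible with 1 library per group, and none is reported.

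For the closing section, differences in retention between peak classes were averaged over strata of 10 score groups and 5 width groups, with Mantel-Haenszel weights, and recomputed leaving out each chromosome in turn. Where X was the class compared, only the autosomes were left out in turn. The code was tested on simulated data: in a list simulated on the 113841 DMSO H3K79me2 peaks, a difference set to -15 points came out at -14.76 and one set to 0 at -0.10, and a ratio of shared to expected losses set to 1 came out at 1.004. Overlap counts equalled those of bedtools 2.31.1 in 10 of 10 comparisons. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

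Alternatives set before the data were examined were a stricter score (peaks at or above the median score of the reference library, in both libraries), equal numbers of top-scoring peaks, an overlap of at least 50% of the reference peak, joining of peaks at most 1 kb apart, autosomes only, and a window change of 25 points.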

Results

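The data describe chromatin of MV4;11, an established human leukemia cell line that carries an MLL fusion protein. The cells had been grown with the vehicle DMSO (0.1%), with 500 nM of I-BET151, with 5 µM of SGC0946, or with both compounds together. I-BET151 is an inhibitor of the BET bromodomain proteins, which bind acetylated histone tails. SGC0946 is an inhibitor of DOT1L, the enzyme that methylates lysine 79 of histone H3. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done for 4 targets: dimethylated lysine 79 of histone H3 (H3K79me2, a mark of transcribed gene bodies), RNA polymerase II (Pol II), acetylated lysine 27 of histone H3 (H3K27ac, a mark of active promoters and enhancers) and acetylated lysine 5 of histone H4 (H4K5ac). H3K79me2 and Pol II were profiled under all 4 treatments, H4K5ac with DMSO and SGC0946, and H3K27ac with DMSO only. Each combination of target and treatment had 1 library, so no difference between treatments below has a replicate error or a p-value. Intervals given with percentages are 95% exact binomial intervals and cover the counting of peaks only. Read depth of the libraries is unknown here, and the length of a peak list moves with depth.

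The lists held 113841 H3K79me2 peaks covering 133.7 Mb with DMSO, 106271 covering 141.3 Mb with I-BET151, 101333 covering 110.3 Mb with SGC0946 and 94002 covering 101.4 Mb with the combination. For Pol II they held 119357 peaks covering 81.6 Mb, 95509 covering 57.5 Mb, 102788 covering 61.2 Mb and 34439 covering 17.3 Mb in the same order. H4K5ac had 69422 peaks (41.2 Mb) with DMSO and 79206 (43.5 Mb) with SGC0946, and H3K27ac had 67350 peaks (67.9 Mb) with DMSO. Positions are given on the hg19 build, counted from 1.

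**Figure D1:**
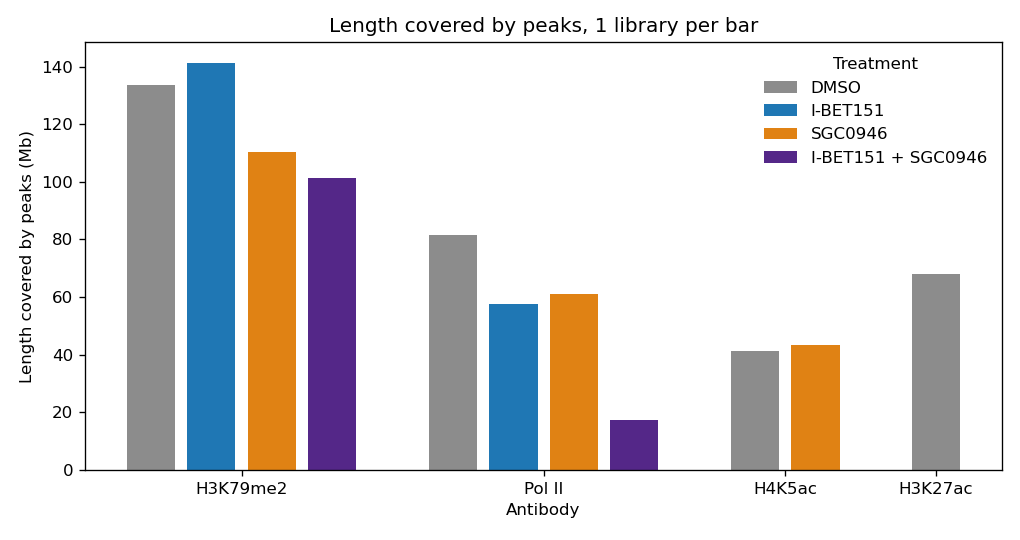
Length covered by peaks, in Mb, in each of the 11 libraries, grouped by antibody and coloured by treatment; each bar is 1 library and has no error. The Pol II bar of the combination (17.3 Mb) is the lowest, and H3K79me2 is lower with SGC0946 (110.3 Mb) than with DMSO (133.7 Mb).

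In vehicle-treated cells, Pol II lay more often on H3K79me2 than on the acetylation marks. Of the 119357 DMSO Pol II peaks, 41.7% (41.4 to 42.0) were overlapped by an H3K79me2 peak, 21.3% (21.0 to 21.5) by an H3K27ac peak and 17.5% (17.3 to 17.7) by an H4K5ac peak. Randomly shifted peaks gave means of 6.76%, 3.96% and 3.15%, in the order of the lengths the lists cover (133.7, 67.9 and 41.2 Mb). The higher share on H3K79me2 thus goes in large part with its longer list. The acetylation marks lay largely on each other, with 73.4% (73.1 to 73.8) of H4K5ac peaks overlapped by H3K27ac and 55.1% (54.8 to 55.5) of H3K27ac peaks overlapped by H4K5ac. H3K79me2 formed the broadest domains: 1662 of its DMSO peaks were at least 10 kb wide, against 414 for Pol II, 200 for H3K27ac and 2 for H4K5ac. The widest H3K79me2 domain, chosen after its width was seen, was on chromosome 16, 89372247 to 89507327 (135.1 kb). The highest-scoring H3K79me2 peak lay on chromosome 19, 49119324 to 49122469 (score 158.0), and the highest-scoring Pol II peak on chromosome 17, 18966248 to 18968085 (score 625.3). With peaks at most 1 kb apart joined first, the shares of Pol II peaks on H3K27ac and on H4K5ac were 32.2% and 29.0%.

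The comparison of SGC0946 with DMSO addressed where H3K79me2 peaks were still called under DOT1L inhibition. Peaks were called per library, so a fall in H3K79me2 common to all sites was not tested. H3K79me2 covered 82.5% of its DMSO length with SGC0946, and 60.9% (60.6 to 61.2) of the DMSO peaks were overlapped by a peak of the SGC0946 library, against 6.00% for randomly shifted peaks. That length includes new peaks, since 20.4% of the SGC0946 peaks had no DMSO peak. Of the bases in DMSO peaks, 69.6% were still covered. Narrow peaks and broad domains differed: of the bases in DMSO peaks under 1 kb wide, 40.2% were still covered, while in the 1662 domains of at least 10 kb the figure was 90.7%. These broad domains were, however, covered in a median of 4 pieces with SGC0946, against 1 with I-BET151, and the number of peaks at least 10 kb wide was 777 against 1662 with DMSO. The widest H3K79me2 peak measured 62.6 kb with SGC0946. H3K79me2 peaks on H3K27ac were overlapped more often (82.5%, n = 24735) than those off it (54.9%, n = 89106); the former also had a higher median DMSO score (12.2 against 5.00).

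Among windows of 100 kb, 615 had H3K79me2 cover lower by at least 10 percentage points with SGC0946 and 12 had it higher. The largest difference was on chromosome 21, 36200001 to 36300000, where H3K79me2 covered 96.1 kb with DMSO and 53.3 kb with SGC0946. Next came the window on chromosome 4 from 96300001 to 96400000 (75.2 and 34.4 kb) and that on chromosome 2 from 66700001 to 66800000 (79.3 and 40.5 kb). A pair of adjoining windows on chromosome X, 19600001 to 19700000 and 19700001 to 19800000, had 66.8 and 86.7 kb with DMSO and 29.3 and 54.2 kb with SGC0946. On chromosome 17, 25800001 to 25900000, cover was 70.4 kb against 33.9 kb, on chromosome 3, 18200001 to 18300000, it was 91.3 kb against 55.6 kb, and on chromosome 2, 145100001 to 145200000, 52.8 kb against 20.9 kb. With the combination, which also held SGC0946, the chromosome 17 window had 68.0 kb, so its loss was not seen there. The other windows named had 14.4 to 59.2 kb with the combination, each below DMSO. The largest gains were smaller: chromosome 5, 16800001 to 16900000, had 20.0 kb with DMSO and 36.9 kb with SGC0946, and chromosome 8, 130300001 to 130400000, had 3.24 and 19.1 kb. The combination had 25.4 and 4.11 kb in these windows. H3K79me2 covered less with SGC0946 than with DMSO on each of the 23 chromosomes 1 to 22 and X, from 67.8% of the DMSO length on X to 89.0% on chromosome 8. A loss of 25 percentage points was met by 27 of the windows and a gain of that size by none, and the count of 12 higher windows changed to 3 with a stricter score and to 28 with peaks joined within 1 kb.

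The comparison of I-BET151 with DMSO on H3K79me2 addressed whether BET inhibition alters the DOT1L mark. H3K79me2 covered slightly more of the genome with I-BET151, 105.7% of the DMSO length, in 93.4% of the number of peaks. The share of DMSO peaks overlapped was 80.2% (79.99 to 80.5), against 7.07% for shifted peaks. New peaks enter the covered length, since 25.3% of the I-BET151 peaks had no DMSO peak. Of the bases in DMSO peaks, 87.8% were covered. Broad domains of at least 10 kb kept 99.5% of their bases, in a median of 1 piece, while DMSO peaks under 1 kb wide kept 64.0%, so narrow peaks kept less with I-BET151 as well as with SGC0946. The peaks at least 10 kb wide numbered 1970, against 1662 with DMSO. No window had H3K79me2 cover lower by 10 percentage points or more, and 10 had it higher. With peaks at most 1 kb apart joined first, 4 were lower and 34 higher; a stricter score and equal numbers of peaks gave 20 and 22 higher, and none was higher by 25 points. The largest gain was on chromosome 20, 46100001 to 46200000, with 39.6 kb covered with DMSO and 53.6 kb with I-BET151, followed by chromosome 1, 230200001 to 230300000 (31.0 and 42.7 kb) and chromosome 16, 23900001 to 24000000 (27.4 and 39.0 kb). On chromosome 8, 97500001 to 97600000, the window with the largest loss, the cover was 11.3 kb with DMSO and 5.40 kb with I-BET151. In the windows on chromosomes 21 and 2 that stood out with SGC0946, I-BET151 left 97.4 kb and 85.6 kb covered. All 23 chromosomes lay above 100%, from 104.5% on chromosome 19 to 108.6% on X.

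With both compounds, H3K79me2 covered 75.8% of its DMSO length, and 55.4% (55.1 to 55.7) of DMSO peaks were overlapped. Of the bases in DMSO peaks, 64.6% were covered, and 19.2% of the combination's peaks had no DMSO peak. Against SGC0946 alone, the combination covered 92.0% of the length and overlapped 66.6% (66.3 to 66.9) of the peaks. Windows lower by at least 10 points than with DMSO numbered 890, and 10 were higher; relative to SGC0946 alone, 91 were lower and 61 higher, a balance that turned with a stricter score (66 and 82) and with equal numbers of peaks (64 and 76) and widened with peaks joined within 1 kb (196 and 91). Under the same 3 alternatives, the 10 windows higher than with DMSO changed to 5, 21 and 25. The window on chromosome 21 from 36200001 had again the largest difference (96.1 kb with DMSO, 51.9 kb with the combination). The windows on chromosome 3 from 18200001, chromosome 4 from 96300001 and chromosome 2 from 145100001 were also among the 8 largest losses both with SGC0946 and with the combination, which left 50.3, 34.8 and 14.4 kb. On chromosome 10, 74500001 to 74600000, H3K79me2 covered 68.7 kb with DMSO, 67.3 kb with SGC0946 and 31.8 kb with the combination. On chromosome 1, 235900001 to 236000000, the 3 values were 85.8, 55.1 and 42.7 kb. The largest gain was on chromosome 17, 65400001 to 65500000, from 29.8 kb to 56.4 kb. Chromosome X was again lowest, at 62.9% of its DMSO length. At a change of 25 points, 38 windows were lower than with DMSO.

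I-BET151 was compared with DMSO on Pol II to ask where BET inhibition removes the polymerase. Pol II covered 70.5% of its DMSO length with I-BET151, and 47.7% (47.4 to 48.0) of DMSO peaks were overlapped, against 4.41% for shifted peaks. Pol II cover was lower by at least 10 points in 678 windows and higher in 22. Several broad Pol II domains were almost absent with I-BET151. Across 3 adjoining windows on chromosome 3, from 18000001 to 18300000, Pol II covered 95.3, 98.4 and 99.4 kb with DMSO and 13.9, 1.49 and 2.40 kb with I-BET151, while H3K79me2 in the same windows covered 98.5, 97.3 and 93.8 kb with I-BET151. On chromosome 4, 96300001 to 96400000, the 93.5 kb covered with DMSO had no Pol II peak left with I-BET151. Chromosome 7, 92300001 to 92400000, had 96.9 kb with DMSO and 9.79 kb with I-BET151, and chromosome 2 lost cover at 160200001 to 160300000 (91.1 and 11.1 kb), 160300001 to 160400000 (93.6 and 16.4 kb) and 240000001 to 240100000 (83.6 and 6.29 kb). The gains were led by chromosome 6, 26100001 to 26200000 (18.5 kb with DMSO, 39.2 kb with I-BET151), chromosome 19, 5100001 to 5200000 (10.1 and 30.5 kb), chromosome 12, 105500001 to 105600000 (27.2 and 47.1 kb) and chromosome 8, 124300001 to 124400000 (31.8 and 48.0 kb). By chromosome, the Pol II length with I-BET151 ran from 61.4% of that with DMSO on chromosome 3 to 80.9% on chromosome 19. Such lengths include new peaks, and of the bases in DMSO Pol II peaks 50.5% were covered with I-BET151. Of the I-BET151 Pol II peaks, 31.2% had no DMSO peak. The count of 22 windows with higher cover changed to 57 with peaks joined within 1 kb, and none was higher by 25 points.

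**Figure D2:**
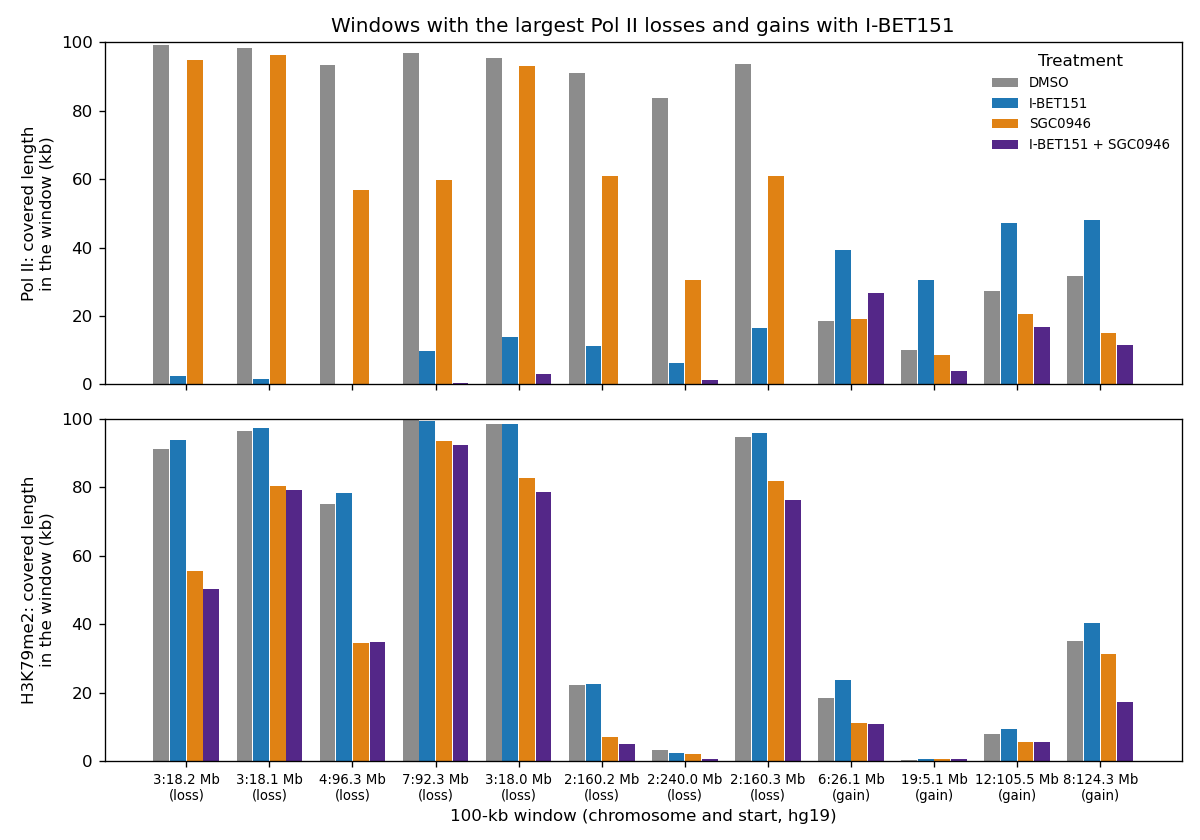
Length covered by Pol II (top) and H3K79me2 (bottom), in kb, under the 4 treatments in the 8 windows of 100 kb with the largest Pol II loss and the 4 with the largest gain with I-BET151; each bar is 1 library. On chromosome 3 from 18200001, Pol II covers 99.4 kb with DMSO, 2.40 kb with I-BET151 and 95.0 kb with SGC0946, while H3K79me2 covers 93.8 kb with I-BET151 and 55.6 kb with SGC0946.

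Pol II peaks on and off H3K27ac differed in how often they were overlapped with I-BET151, in large part along with their DMSO score and width. Of the 16232 DMSO Pol II peaks on both H3K27ac and H3K79me2, 69.8% (69.1 to 70.5) were overlapped by an I-BET151 peak, and of the 9139 on H3K27ac only, 65.8% (64.8 to 66.8). For the 33550 peaks on H3K79me2 only the share was 38.1% (37.6 to 38.7), and for the 60436 on neither mark it was 44.3% (43.9 to 44.7). The classes on H3K27ac had higher median DMSO scores (8.95 and 6.61) than the other classes (4.37 and 4.41). The raw difference on minus off H3K27ac was 26.2 points, and at equal DMSO score and width it was 7.29 points. Retention rose with the DMSO score, from 25.4% of the peaks in the lowest score decile to 96.7% in the highest.

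**Figure D3:**
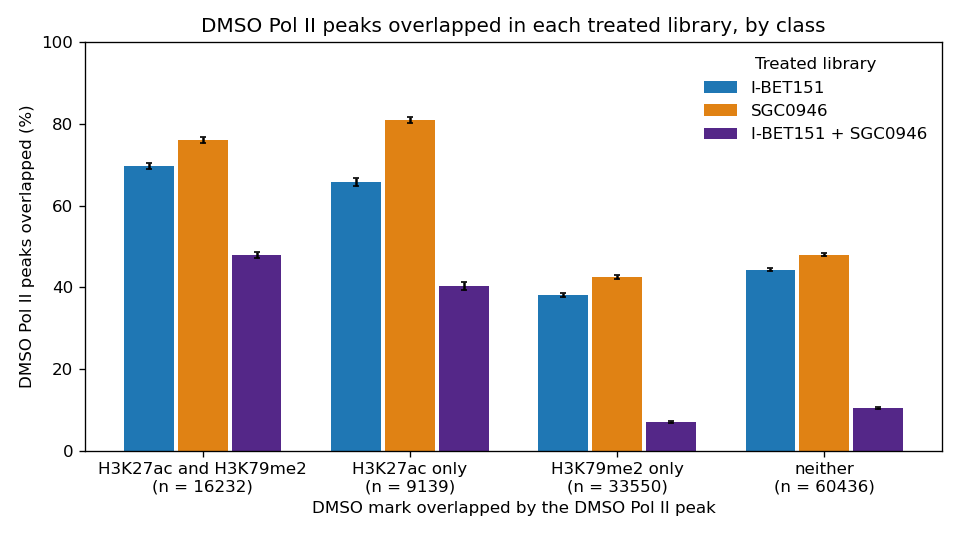
Share of DMSO Pol II peaks overlapped by a peak of each treated library, in percent, by the DMSO mark on which the peak lies; bars are shares, whiskers are 95% exact binomial intervals and n is the number of peaks. The combination overlaps 47.8% of the peaks on both marks and 7.06% of those on H3K79me2 only.

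SGC0946 was compared with DMSO on Pol II to ask whether DOT1L inhibition acts on the polymerase at the same places. Pol II covered 74.97% of its DMSO length with SGC0946, and 52.8% (52.5 to 53.1) of DMSO peaks were overlapped, against 4.58% for shifted peaks. Pol II cover was lower by at least 10 points in 399 windows and higher in 4. The window on chromosome 2 from 240000001 to 240100000 had the largest loss (83.6 kb with DMSO, 30.5 kb with SGC0946) and was among the 8 largest with I-BET151 too. It was followed by chromosome 5, 177800001 to 177900000 (67.0 and 23.1 kb), chromosome 12, 104900001 to 105000000 (50.4 and 8.31 kb) and chromosome 4, 87900001 to 88000000 (52.5 and 11.8 kb). All 8 windows with the largest SGC0946 losses also had less Pol II with I-BET151 than with DMSO. In those on chromosomes 5, 12 and 4, I-BET151 left 0.216, 10.2 and 16.8 kb. Less Pol II with I-BET151 was common, however. Of the 4054 windows with at least 5 kb of Pol II with DMSO, 16.1% had more with I-BET151. The median length with I-BET151 in these windows was 71.3% of that with DMSO. Both comparisons also share the DMSO library, so the 8 windows are not read as a shared effect. Of the windows with the largest I-BET151 losses, that on chromosome 4 from 96300001 had 93.5 kb with DMSO and 56.9 kb with SGC0946. Chromosome 7 from 92300001 had 96.9 and 59.7 kb. Chromosome 2 had 91.1 and 61.0 kb from 160200001, and 93.6 and 61.0 kb from 160300001. The region that lost most with I-BET151 differed: on chromosome 3 from 18000001 to 18300000, Pol II still covered 93.1, 96.4 and 95.0 kb with SGC0946. Broad Pol II domains also differed between the compounds, since in the 414 DMSO domains of at least 10 kb SGC0946 left 94.3% of the bases covered and I-BET151 left 81.5%. By class, 76.1% (75.4 to 76.7) of the Pol II peaks on both marks and 81.0% (80.2 to 81.8) of those on H3K27ac only were overlapped, against 42.5% (41.9 to 43.0) on H3K79me2 only and 48.0% (47.6 to 48.4) on neither. On minus off H3K27ac, the raw difference was 31.8 points and that at equal DMSO score and width 13.92 points. The largest gain was on chromosome 4, 181100001 to 181200000, from 21.4 kb to 36.7 kb. A change of 25 points was met by 69 windows with SGC0946 and by 129 with I-BET151, and 679 were lower by 10 points with SGC0946 when peaks at most 1 kb apart were joined.

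Pol II peaks were far fewer with both compounds than with either alone. The combination had 34439 peaks, 28.9% of the DMSO number, covering 21.2% of the DMSO length, 30.0% of the I-BET151 length and 28.2% of the SGC0946 length. It overlapped 16.9% (16.7 to 17.1) of DMSO peaks, 22.8% (22.5 to 23.04) of I-BET151 peaks and 21.2% (21.0 to 21.5) of SGC0946 peaks, against 1.62%, 1.64% and 1.60% for shifted peaks. Of the combination's own peaks, 10.3% (10.03 to 10.7) had no DMSO peak, a share that is not set against those of the longer lists. Peaks at least 10 kb wide numbered 15, against 414 with DMSO. This library was also the only one of the 11 with peaks on mitochondrial DNA, 8 of them, which covered 14.9 kb. With the 34439 top-scoring peaks taken from each library, 44.9% of these DMSO peaks were overlapped. The covered length of the combination was then 35.0% of that of the shortened DMSO list. With an overlap of at least 50% of the DMSO peak required, the share was 7.95%.

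The Pol II list of the combination, the shortest, had a higher share on H3K27ac than the longer lists. Of the covered bases, 42.9% lay on DMSO H3K27ac peaks, against 22.4% with DMSO, 24.3% with I-BET151 and 26.9% with SGC0946. The combination overlapped 47.8% (47.1 to 48.6) of the DMSO Pol II peaks on both marks and 40.3% (39.3 to 41.3) of those on H3K27ac only. On H3K79me2 only it overlapped 7.06% (6.79 to 7.34), and on neither mark 10.5% (10.3 to 10.8). Strong peaks lie on H3K27ac more often in DMSO as well (29.8% of Pol II peaks with a stricter score, against 21.3%), and the raw difference of 35.8 points on minus off H3K27ac was 16.08 points at equal DMSO score and width. Of the DMSO peaks in the highest score decile, 81.7% were overlapped, and of those in the lowest, 3.03%. Pol II cover was lower by at least 10 points than with DMSO in 2126 windows and higher in none. In the windows on chromosome 3 from 18100001 and 18200001, chromosome 4 from 96300001 and chromosome 2 from 160300001, no Pol II peak was left, where DMSO had 98.4, 99.4, 93.5 and 93.6 kb. On chromosome 1, Pol II covered 99.0 kb with DMSO, 90.4 kb with SGC0946, 29.9 kb with I-BET151 and 4.04 kb with the combination from 44300001 to 44400000. Another window of chromosome 1, 235900001 to 236000000, had 98.8, 90.9, 53.7 and 6.22 kb in the same order. The few windows with more Pol II than with DMSO included 26100001 to 26200000 (18.5 and 26.7 kb) and 26200001 to 26300000 (19.3 and 24.3 kb) on chromosome 6, and 149800001 to 149900000 on chromosome 1 (32.7 and 35.5 kb). These 3 windows had 39.2, 31.0 and 42.6 kb with I-BET151. On chromosome 2, 145100001 to 145200000, Pol II covered 57.1 kb against 62.2 kb with DMSO, while H3K79me2 there went from 52.8 kb to 14.4 kb. Equal numbers of peaks gave 880 windows lower by 10 points, and 507 were lower by 25 points.

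**Figure D4:**
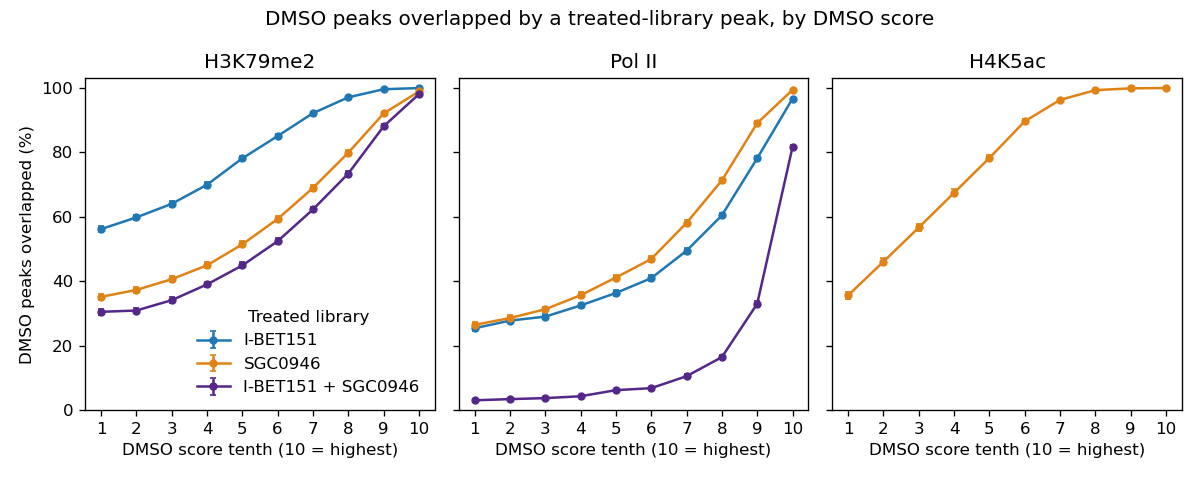
Share of DMSO peaks overlapped by a peak of each treated library, in percent, by decile of the DMSO score (10 is the highest), for H3K79me2, Pol II and H4K5ac; points are shares and whiskers are 95% exact binomial intervals. For Pol II the combination runs from 3.03% to 81.7%, below I-BET151 (25.4% to 96.7%) in each decile.

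I-BET151 and SGC0946 were also compared with each other through the DMSO peaks that each left without an overlapping peak. For Pol II, 62445 DMSO peaks were lost with I-BET151, 56334 with SGC0946 and 42180 with both. Independent losses would give 29473, independent losses within deciles of the DMSO score 36087, and those within groups of equal score and width 37214. For H3K79me2, 22514 were lost with I-BET151, 44537 with SGC0946 and 16147 with both, against 8808, 12655 and 13554. The counts were thus 1.13 and 1.19 times those expected at equal score and width. Both comparisons share the DMSO library, so some or all of this excess may come from DMSO peaks that no other library would hold, and it is not read as a shared effect. Among peaks kept with a stricter score, 20715 and 7626 were lost with both compounds. Directly, 59.5% of I-BET151 Pol II peaks were overlapped by SGC0946 peaks, and 55.7% in the other direction. For H3K79me2 these shares were 59.1% and 81.1%.

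H4K5ac was compared between SGC0946 and DMSO to ask whether DOT1L inhibition lowers histone H4 acetylation. The SGC0946 library had more peaks (79206 against 69422) and covered 105.5% of the DMSO length, and 76.9% (76.6 to 77.3) of DMSO peaks were overlapped, against 3.12% for shifted peaks. Of the bases in DMSO peaks, 77.9% were covered, and 30.3% of the SGC0946 peaks had no DMSO peak. The DMSO list held 8868 peaks of score 50 or more and the SGC0946 list 3942. These scores depend on each library's depth. DMSO H4K5ac peaks on H3K27ac were overlapped in 88.2% of cases (88.0 to 88.5) and those off it in 45.7% (45.0 to 46.4), with median DMSO scores of 14.6 and 4.78. For peaks with and without H3K79me2 the shares were 82.8% (82.3 to 83.3) and 74.3% (73.9 to 74.7), but the median DMSO scores were 22.5 and 7.84. At equal DMSO score and width the direction turned, and peaks with H3K79me2 were overlapped less often, by -4.46 points. H4K5ac cover was lower by at least 10 points in 3 windows and higher in 5, counts that changed to 2 and 0 with a stricter score, 3 and 2 with equal numbers of peaks and 9 and 31 with peaks joined within 1 kb. The 3 were on chromosome 19, 36700001 to 36800000 (25.8 kb with DMSO, 5.71 kb with SGC0946) and 37700001 to 37800000 (15.6 and 3.66 kb), and on chromosome 6, 7100001 to 7200000 (26.9 and 14.1 kb). H4K5ac peaks are narrow, and 2420 windows held at least 5 kb of H4K5ac with DMSO, so few windows could fall by 10 points. In those 2420 windows the median length with SGC0946 was 96.4% of that with DMSO, and 41.7% were above 100%. In adjoining windows on chromosome 9, 80500001 to 80600000 and 80600001 to 80700000, H4K5ac went from 10.2 and 13.0 kb to 2.56 and 3.55 kb and Pol II from 69.0 and 50.2 kb to 28.7 and 24.2 kb, while H3K79me2 had 99.3 and 51.3 kb with DMSO and 95.6 and 51.0 kb with SGC0946. The largest gains were on chromosome 13, 26300001 to 26400000 (2.85 and 15.4 kb) and chromosome 1, 66800001 to 66900000 (9.37 and 21.9 kb). Chromosome 19 was lowest, at 91.1% of its DMSO length, and chromosome 13 highest, at 119.4%. The direction of the covered length turned with the peaks kept, to 96.1% with a stricter score and to 99.99% with equal numbers of peaks.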

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

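All 6 tests in this part and in the other observations were written down before their values were seen, on patterns already noticed in the same data. The reading of 4 of them was changed afterwards, and the comparisons of the Pol II tests with the SGC0946 and I-BET151 libraries were chosen only after the result was seen.

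Under I-BET151 the covered length moved in opposite directions for the 2 targets, to 105.7% of DMSO for H3K79me2 and to 70.5% for Pol II. With SGC0946 it was 82.5% for H3K79me2 and 74.97% for Pol II, and 105.5% for H4K5ac, whose direction turned with the peaks kept (96.1% with a stricter score). With 1 library per group these differences were not tested.

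Peaks on mitochondrial DNA, outside the chromosomes compared, appeared in 1 library. The Pol II library of the combination had 8, covering 14.9 kb between positions 231 and 16392 with scores of 3.47 to 10.03, and the 10 other libraries had 0.

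The same library has far fewer Pol II peaks (34439) than the other 3 (95509 to 119357). If lower depth or enrichment were the whole cause, retention should depend on the score and width of the DMSO peak alone, yet at equal score and width peaks on H3K27ac were overlapped more often than those off it by 16.08 points (15.85 to 16.26 without each chromosome in turn). This was to count against depth, but the SGC0946 library, with 102788 peaks, shows 13.92 points and I-BET151 7.29, so the bound of 5 points was not specific to the short list. For a loss tied to I-BET151, windows were split by whether their Pol II length with I-BET151 was under 50% of that with DMSO. Those under it had a lower length in the combination, as a percentage of DMSO, by -16.95 points (-17.11 to -16.72), but a split by SGC0946 gave -14.37. Depth, enrichment and an effect of the combined treatment cannot be told apart here, because the treatment and the library are the same.

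H3K79me2 with SGC0946 was lowest on chromosome X (67.8% of the DMSO length). Weaker or narrower DMSO peaks on X were weighed as the cause. At equal score and width, 3373 peaks on X were overlapped less often than those on autosomes by -8.65 points (-8.87 to -8.48), with -5.65 in the combination and 0.11 with I-BET151, which argues against peak strength as the whole cause. The range in brackets leaves out the autosomes in turn and never X, so it does not show how stable the X value is. Among 23 chromosomes compared with the rest, the next was chromosome 19 at -4.80 points and the highest chromosome 8 at 4.002. Copy number and a biological difference of X were not tested, and the pattern rests on 2 libraries with SGC0946.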

How the results depend on the processing

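The alternatives were set before the data were examined, and the cause of each difference was not tested unless its construction shows it. The covered lengths of H3K79me2 and Pol II stayed on the same side of 100% under each alternative that gives one. H4K5ac with SGC0946 did not: its 105.5% of the DMSO length became 96.1% with a stricter score and 99.99% with equal numbers of peaks. Read depth is unknown, and it limits each comparison of list lengths. No paired analysis was possible because each group has 1 library and no result comes from a test. The alternatives on genes (first 10 kb, start-site windows of 3 kb) were not run, since no annotation of the build was used.

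With a stricter score, the share of DMSO peaks overlapped became 81.9% (I-BET151) and 57.6% (combination) for H3K79me2, 49.3%, 55.4% (SGC0946) and 20.6% (combination) for Pol II and 80.4% for H4K5ac. The combination overlapped 70.9% of SGC0946 H3K79me2 peaks, 27.8% of I-BET151 and 25.6% of SGC0946 Pol II peaks. DMSO Pol II peaks lay on H3K79me2 in 39.0%, on H3K27ac in 29.8% and on H4K5ac in 25.9%. Peaks lost with both compounds numbered 7626 for H3K79me2 and 20715 for Pol II, fewer because fewer peaks enter.

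With equal numbers of peaks, the shares for H3K79me2 were 81.9% (I-BET151), 64.1% (SGC0946), 60.6% (combination) and 68.7% (combination against SGC0946). For Pol II they were 53.0%, 57.0%, 44.9%, and 50.5% and 48.8% for the combination against I-BET151 and SGC0946, with covered lengths of 35.0%, 46.9% and 44.6% for the 3 comparisons of the combination. For H4K5ac the share was 73.3%. Pol II lay on H3K27ac in 29.0% and on H4K5ac in 24.9%, and 880 windows had lower Pol II cover with the combination than with DMSO, against 2126.

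With an overlap of at least 50% of the reference peak, a narrower definition that can only lower a share, H3K79me2 gave 70.6% (I-BET151), 48.3% (SGC0946), 40.8% (combination) and 53.1% (combination against SGC0946). Pol II gave 34.3%, 38.1%, 7.95%, and 12.4% and 11.5% against the single compounds, and H4K5ac 71.2%. Pol II lay on H3K79me2 in 33.3%, on H3K27ac in 18.2% and on H4K5ac in 13.3%, and 25349 H3K79me2 peaks were lost with both compounds.

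With peaks joined within 1 kb, H3K79me2 gave 74.7%, 66.4%, 59.1% and 63.6% in the same order, Pol II 50.5%, 53.8%, 26.2%, 31.2% and 29.9%, and H4K5ac 78.98%. Pol II lay on H3K79me2 in 44.4%, on H3K27ac in 32.2% and on H4K5ac in 29.0%. Windows with lower cover numbered 4 for H3K79me2 with I-BET151, 679 for Pol II with SGC0946 and 9 for H4K5ac, and 5946 H3K79me2 and 18517 Pol II peaks were lost with both compounds.

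On autosomes only, the H3K79me2 share with SGC0946 was 61.2%, and all other results stayed within their margin. A window change of 25 points left 27 (SGC0946) and 38 (combination) windows with lower H3K79me2 cover, 129, 69 and 507 with lower Pol II cover (I-BET151, SGC0946, combination) and 0 with lower H4K5ac cover.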

Other observations

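The 6 tests of this closing section were set before their values were seen, and the reading of 4 of them, the 2 on H4K5ac and the 2 on the Pol II combination, was changed afterwards. The H4K5ac value over all peaks was brought in only after the result was seen.

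H3K27ac in vehicle-treated cells was used above only as a place for other marks. Its 5 highest-scoring peaks lay on chromosome 19 at 51221520 to 51228114 and 1852543 to 1859130, on chromosome 8 at 37677447 to 37681830 and 130665529 to 130686428, and on chromosome 3 at 50635420 to 50644551, with scores of 474.2 to 422.1. The widest H3K27ac domain, chosen after its width was seen, was on chromosome 12 from 11894852 to 11968390 (73.5 kb), and 200 peaks of at least 10 kb held 4.71% of the covered length. For H3K79me2 the 1662 peaks of that width held 23.1%.

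Most bases of very broad H3K79me2 domains stayed under peaks with SGC0946 and with the combination. The 8 widest with DMSO, chosen after their widths were seen, ran from 69.9 to 135.1 kb. No H3K79me2 peak with SGC0946 was wider than 62.6 kb, so these domains were covered in pieces. The share of bases covered does not measure the level of the mark. On chromosome 16, 89372247 to 89507327, 96.2% of the bases were covered with SGC0946 and 98.2% with the combination. On chromosome 2, 145179436 to 145255437, lowest of the 8, the shares were 90.7% and 87.4%. A Pol II domain on chromosome 2, 145137807 to 145255436 (117.6 kb), the widest with DMSO, was found again with SGC0946 at 145138241 to 145255416 (117.2 kb). With I-BET151 a peak there ran from 145198114 to 145251550 (53.4 kb), and the widest Pol II peak of the combination at any place was 41.4 kb.

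The 5 highest-scoring peaks of each Pol II library were at most 4.66 kb wide. On chromosome 1, a peak was among the 5 highest in each of the 4 Pol II libraries, starting at 147993199 with DMSO, 147993113 with I-BET151, 147993368 with SGC0946 and 147993485 with the combination. The other top peaks of the combination, led by chromosome 1, 148240691 to 148242419, were not among the 5 highest of another Pol II library.

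H4K5ac with SGC0946 had more peaks than with DMSO and fewer of score 50 or more (3942 against 8868). For a lower enrichment of the whole library, DMSO peaks of score 50 or more should be overlapped by such a peak alike with and without H3K79me2, and at equal score and width the difference was -0.58 points (-1.53 to -0.13). Over all H4K5ac peaks, however, those with H3K79me2 were overlapped less often by -4.46 points (-4.75 to -4.19), outside the 3 points set for a like share and short of the 5 set against it, so this explanation stays open. Whether H4K5ac was lost where H3K79me2 was lost was examined through overlap by any SGC0946 peak. H4K5ac peaks whose H3K79me2 was lost were overlapped less often as counted (77.8% against 83.9%). At equal score and width they were overlapped more often, by 3.10 points (2.71 to 3.38). The sign was used in place of the bound of 3 points only after the value was seen. In the 2 highest score deciles 99.9% and 100% of H4K5ac peaks were overlapped, so overlap cannot show a fall in the score of strong peaks. For these the explanation stays open. An effect of SGC0946 on H4K5ac common to all sites was not tested.

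A further hypothesis was that Pol II is lost in the windows that lost H3K79me2 with SGC0946. Among windows with at least 5 kb of Pol II and 20 kb of H3K79me2 with DMSO, 490 had lost at least 10 points of H3K79me2. The other 1115 had lost less or none. At equal DMSO cover, Pol II length with SGC0946, as a percentage of DMSO, was lower in the 490 windows by -1.78 points (-2.26 to -1.29). This was under the 3 points set as the bound, and with I-BET151 the difference was -4.28 points. A difference of the 5 points set for the test was thus not seen between larger losses of H3K79me2 and smaller or no losses. Of all windows with at least 5 kb of H3K79me2 with DMSO, 10.7% had more with SGC0946, and the median was 81.0%. As most windows lost some H3K79me2, the test cannot tell whether Pol II fell wherever the mark fell.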
